A study of Mus musculus with 17 samples.

How the data were processed

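RNA from mouse hearts labelled as adult cardiomyocytes was sequenced at days 2, 4 and 6 after tamoxifen in a control group (genotype given as WT, tamoxifen treated) and in a group overexpressing Ino80 (OE). Ino80 is the ATPase of the INO80 chromatin remodelling complex. The 17 libraries fell into 6 groups of 3, except the day 4 control group with 2. Per the labels, 1 ug of total RNA per library went into a KAPA mRNA HyperPrep kit. Per the submitters' processing notes, reads were aligned with STAR to mouse build mm10 and counted with featureCounts, and DESeq2 was used. The STAR and DESeq2 versions are not given in the sources used here. Per the file headers, featureCounts 1.6.2 counted read pairs per gene with strand setting 0, which ignores strand. The deposited values are whole-number counts per gene and library, with no normalization. Gene symbols, positions and lengths came from the same count tables.

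Each library held 8626018 to 28256529 counts, so that 3 counts, the floor used for a gene at 0, equalled 0.106 to 0.348 CPM (counts scaled to a common library total) per library. Counting intervals and floors cover counting error alone. Intervals of list medians come from t-tests over libraries, as the genes of a list are correlated; resampling the genes was tried first. Of 24062 genes in the tables, 9458 with low counts in the groups were removed with edgeR's filterByExpr, which took out 0.0336% of the counts and left 14604. None of the genes of the mitochondrial genome was in the tables (0 symbols), so the list of mitochondrially encoded genes was not tested.

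Analyses ran in R 4.3.3. Libraries were scaled with TMM, and CPM below are on that scale. A quasi-likelihood model with robust spread was fitted to all 17 libraries with edgeR 4.0.16, 1 mean per group. Its common biological coefficient of variation was 0.233, with 11 residual degrees of freedom per gene. Tests compared OE with control at each day, the OE effects of each pair of days, and the control group at days 4 and 6 with that at day 2. P-values were adjusted by Benjamini-Hochberg over the 14604 genes, and a gene counted as changed at an adjusted p under 0.05. Log2 fold changes carry an approximate standard error (SE), and CPM carry the standard deviation (SD) over libraries. The SE was derived from the test, as the size of the log2 fold change over the square root of its F statistic. It is not an estimate given by the model.

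Of 36 gene lists written before the data were examined, 35 were tested with limma 3.58.1's camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over the lists. Camera was also run with an estimated correlation, beside fry. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. List symbols Ccn2, Ccn1 and Adgre1 were matched to Ctgf, Cyr61 and Emr1. The rule for named genes was also written before the data were examined. It took all INO80 complex subunits. At each day it took the 8 largest rises and 8 largest falls among changed genes with a mean log2 CPM of at least 1, no gene-model symbol and no overlap between the groups' libraries. From each list it took up to 4 changed members with the smallest p or, where none changed, 2 abundant members as values. For each difference between days it took the 4 genes per direction with the smallest adjusted p, and for control days the 4 largest changes per direction. The text stops short of the full set in places, keeping this order. Esr1 was reached by this rule at each day; A1cf and Gt(ROSA)26Sor were chosen after their values were seen.

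Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE size factors, no filter on low counts, a fit to the libraries of the compared days alone (to the control libraries of all days for control comparisons), a replicate-number block within each day (across days, in the control libraries alone, for control comparisons), a sex covariate, camera with an estimated correlation, fry, and leaving out each library in turn. Added after the data were seen were the omission of 4 libraries that stood apart and a correction for gene length. The alternative with the mitochondrial list was not run. The tests were also tried on simulated data, and other splits of the libraries into groups of the same sizes were counted. The labels do not say that replicates are separate animals. Day 4 OE replicate 1, with a female pattern, must come from another animal than replicates 2 and 3 of its group; in the other groups the p-values may measure technical spread alone. Replicate counts of a group differed beyond counting error (chi-square per degree of freedom 5.06 to 189).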

Results

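The data were read counts per gene from 17 libraries of mouse adult cardiomyocytes, taken from hearts 2, 4 and 6 days after tamoxifen. At each day an Ino80-overexpressing group (OE) was set against a tamoxifen-treated control group, and the question, per the series title, was what Ino80 overexpression does to gene expression. There were 3 OE and 3 control libraries at days 2 and 6, and 3 OE and 2 control libraries at day 4. At day 2 control libraries held 12525822 to 23339483 counts and OE libraries 13457943 to 23332875. The ranges were 20463828 to 28256529 and 19610349 to 25950369 at day 4, and 8626018 to 11680058 and 12362153 to 15202234 at day 6.

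Ino80 RNA was far higher in every OE library than in any control library of its day. Ino80, on chromosome 2 of mm10 from 119373042 to 119477629, was counted at 2593 ± 1112 CPM (mean ± SD, n = 3) in OE at day 2, against 43.3 ± 7.49 CPM in control (n = 3). At day 4 its level was 5099 ± 899.5 CPM (n = 3) against 41.6 ± 6.34 CPM (n = 2), and at day 6 2254 ± 1292 CPM against 35.6 ± 1.12 CPM (n = 3 each). The ratios of means were 59.9, 122 and 63.4, and edgeR's log2 fold changes were 5.90 ± 0.49, 6.94 ± 0.62 and 5.99 ± 0.49 (SE; adjusted p = 5.72e-06, 3.67e-06 and 9.38e-07). An exact 2-sided permutation test of CPM gave p = 0.1 at each day, the smallest that these group sizes allow. Among the other 15 subunits of the INO80 complex, changes were small: Ino80c rose by 0.94 ± 0.16 and Ruvbl1 by 0.89 ± 0.21 at day 4, and Actr8 fell at day 6 (-0.76 ± 0.11; edgeR adjusted p = 0.000522, 0.00495 and 8.59e-05). Of all 16 subunits, Ino80 included, 1 rose and 1 fell at day 2, 5 rose and 2 fell at day 4, and 2 rose and 2 fell at day 6. Adjusted over the list alone, the counts were the same at days 2 and 4, and 2 rose and 1 fell at day 6. Camera did not call the list at any day (adjusted p = 0.993, 0.19 and 0.837), and at day 2 its median of -0.11 and its mean of 0.29 differed in sign. The only subunit besides Ino80 that passed at day 2 was Ruvbl2 (-0.47 ± 0.14, edgeR adjusted p = 0.032). That call ended without any 1 of control replicates 2 and 3 and OE replicates 1 and 2 of day 2 (adjusted p 0.092, 0.0595, 0.119 and 0.0603), and in a fit to day 2 alone (0.296).

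Counts assigned to Esr1, the oestrogen receptor gene on chromosome 10 from 4612046 to 5003761, also set the groups apart. They came to 1397 ± 512, 769.6 ± 225 and 197 ± 82.4 CPM in OE at days 2, 4 and 6, against 1.14 ± 0.708, 2.78 ± 2.48 and 0.702 ± 0.227 CPM in control (mean ± SD). EdgeR's log2 fold changes were 10.24 ± 0.70, 8.08 ± 0.76 and 8.09 ± 0.69 (SE; adjusted p = 1.16e-06, 5.41e-06 and 1.21e-06). A pair of loci looked up after their values were seen moved alike. Gt(ROSA)26Sor, on chromosome 6 from 113067429 to 113077244, had 19.8 ± 11.2, 34.2 ± 7.95 and 17.9 ± 6.42 CPM in OE and 2.13 ± 0.981, 1.85 ± 1.24 and 0.24 ± 0.242 CPM in control. A1cf, an RNA-editing cofactor gene on chromosome 19 from 31868761 to 31949406, had 0 counts in each control library, which put OE at least 9.41, 22.2 and 2.47-fold higher against a floor of 3 counts per library. Whether these counts come from the endogenous genes or from sequence carried by the OE line could not be read from gene counts, and the same holds for Ino80.

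**Figure D1:**
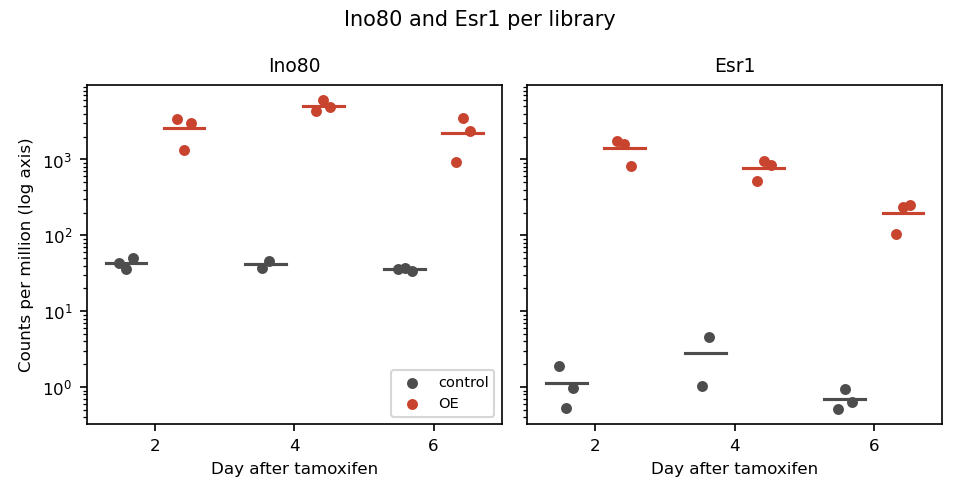
CPM of Ino80 and Esr1 in each library on a log axis, by group and day; bars are group means. Every OE library lies above every control library for both genes.

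OE and control libraries of each day lay apart. In a principal component analysis, component 1 held 58.9% and component 2 16.0% of the variance. Control libraries lay between -51.9 and -40.0 on component 1, except day 2 control replicate 2 at -14.3, and OE libraries of days 4 and 6 between 42.7 and 74.6. OE libraries of day 2 lay between these on component 1 (-10.7 to -2.85) and apart on component 2 (38.5 to 55.0). By Xist and Y-linked genes 16 libraries had a male pattern, and day 4 OE replicate 1 alone a female one. Besides that library, day 2 control replicate 2, day 2 OE replicate 3 and day 6 OE replicate 1 stood apart from the others of their groups, and each count of changed genes was also computed without these 4.

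**Figure D2:**
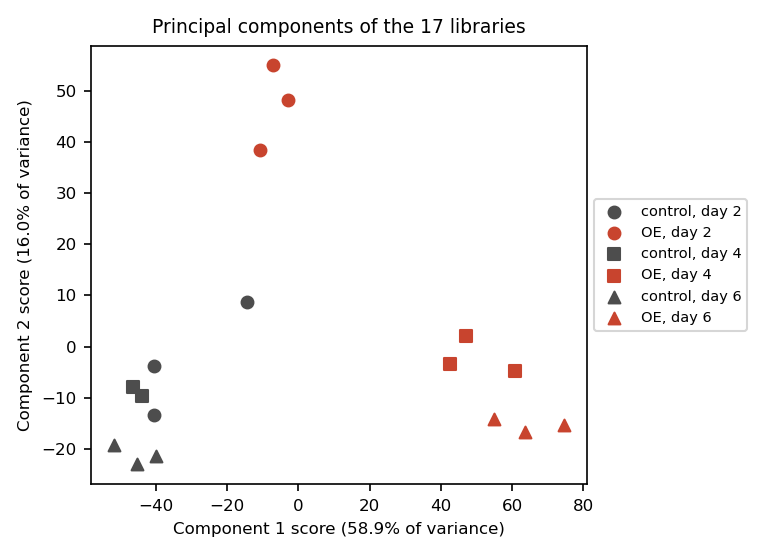
Libraries on the first and second principal components of log2 CPM, coloured by group and day; the axes carry 58.9% and 16.0% of the variance. OE libraries of days 4 and 6 lie at 42.7 or more on the first axis and control libraries at -14.3 or less.

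At day 2, the calcium handling gene Pln and the metabolic regulator Ppargc1a were lower in OE cardiomyocytes and the stress cytokine gene Gdf15 was higher (n = 3 and 3). Phospholamban (Pln), which restrains the calcium pump of the sarcoplasmic reticulum, went from 4512 ± 2026 CPM in control to 327 ± 73.1 CPM in OE, a log2 fold change of -3.79 ± 0.39 (SE; edgeR adjusted p = 2.05e-05). Ppargc1a, a coactivator of mitochondrial biogenesis, went from 323 ± 136 to 21.9 ± 5.52 CPM (-3.88 ± 0.38, edgeR adjusted p = 1.42e-05). Gdf15, a cytokine released by stressed cells, rose from 2.35 ± 1.07 to 26.1 ± 7.30 CPM (3.49 ± 0.35, edgeR adjusted p = 1.67e-05). By edgeR, 2781 of 14604 genes changed (19.0%), 1350 higher and 1431 lower in OE, of which 638 and 692 by at least 2-fold. For 3969 genes (27.2%) all OE libraries lay on 1 side of all control libraries, where chance gives 10%.

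Part of the calcium handling list fell at day 2. Of 26 calcium handling genes, 12 fell and 14 did not pass (13 fell adjusted over the list alone), with a median log2 fold change of -0.56. Triadin (Trdn), which couples the calcium release channel to its store, fell most clearly by p (-2.41 ± 0.20), then Pln. The L-type calcium channel subunits Cacnb2 (-3.21 ± 0.45) and Cacna1c (-2.76 ± 0.41) fell as well. Camera called the list (adjusted p = 0.00484; adjusted p = 0.746 with an estimated correlation). Of 27 cardiac ion channel genes 8 fell and 4 rose (10 and 5 adjusted over the list alone), among them the transient outward current genes Kcnd2 (-3.67 ± 0.49) and Kcnip2 (-2.06 ± 0.30), both lower, and Kcne1 (1.76 ± 0.32), higher. Camera did not call that list (adjusted p = 0.448). Of 26 adult sarcomere genes 5 fell, cardiac actin Actc1 (-1.47 ± 0.33) and Myoz2 (-1.10 ± 0.26) first, and 1 rose (6 and 1 adjusted over the list alone).

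Part of each mitochondrial metabolism list fell at day 2 as well. Of 51 nuclear oxidative phosphorylation genes 18 fell and 33 did not pass (31 fell adjusted over the list alone; median -0.56, and -0.28 with a gene length trend removed, a correction chosen after the data were seen); the complex I gene Ndufs4 (-1.08 ± 0.19) led by p. Of 32 fatty acid oxidation genes 12 fell (18 adjusted over the list alone; median -0.62), with Ppargc1a and the nuclear receptor Ppara (-2.83 ± 0.38) first. Of 23 tricarboxylic acid cycle genes 7 fell (7 adjusted over the list alone; median -0.54), led by malate dehydrogenase Mdh1 (-1.58 ± 0.24). Camera called the 3 lists (adjusted p = 1.61e-11, 4.77e-07 and 0.00011), with adjusted p = 0.807, 0.807 and 0.919 with an estimated correlation. Among 23 cardiac transcription factors 9 fell and 1 rose (10 and 2 adjusted over the list alone; median -0.42). Besides Ppara they included Klf15 (-1.75 ± 0.26), Hand2 (-1.65 ± 0.25) and the oestrogen-related receptor Esrrg (-2.73 ± 0.43); camera gave adjusted p = 0.00072, and adjusted p = 0.807 with an estimated correlation.

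Stress and matrix lists were among those called as higher. Of 25 fetal and stress-response cardiac genes 10 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.42), such as Gdf15 and the intercalated disc gene Xirp1 (3.27 ± 0.53), against a lower Myh7b (-1.66 ± 0.30). Of 27 genes of the ATF4-driven integrated stress response 6 rose and 2 fell (9 and 3 adjusted over the list alone; median 0.50), among them the amino acid transporter Slc7a5 (1.88 ± 0.20), Sesn2 (1.42 ± 0.17) and the alanyl-tRNA synthetase Aars (1.01 ± 0.16). Of 35 extracellular matrix genes 8 rose and 27 did not pass (9 rose adjusted over the list alone; median 0.27), thrombospondin Thbs1 (2.68 ± 0.42) and the collagen cross-linker Lox (1.93 ± 0.34) first. Camera called these 3 lists (adjusted p = 0.000164, 0.0084 and 0.0108), with adjusted p = 0.746, 0.807 and 0.919 with an estimated correlation. Beside these, camera called none of the macrophage, endothelial and fibroblast marker lists, whose medians were -0.34, 0.29 and -0.18 (adjusted p = 0.984, 0.0788 and 0.415). With a replicate-number block camera called the endothelial list as higher (adjusted p = 0.0117; adjusted p = 0.811 with an estimated correlation).

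Of 28 G2/M and mitosis genes 1, the kinetochore gene Cenpf (-2.36 ± 0.36), fell, here and adjusted over the list alone, and 27 did not pass. Camera's call of that list as lower (median -0.55, adjusted p = 0.00484; adjusted p = 0.919 with an estimated correlation) ended without OE replicate 3 (0.219) and without the 4 libraries that stood apart (0.443). Under the naming rule, the largest rises at day 2 were Esr1, the keratin Krt18 (5.96 ± 0.78), Ino80 and the stress-responsive ankyrin Ankrd2 (5.61 ± 0.98), and the largest falls Asb15 (-4.86 ± 0.49) and Cngb3 (-4.45 ± 0.54). In a fit to the 6 libraries of day 2 alone, 423 genes passed, and the calls of Ankrd2 (edgeR adjusted p = 0.0508), Actc1 (0.0855), Myoz2 (0.118) and Ndufs4 (0.0614) ended. Camera's call of the sarcomere list (median -0.39, adjusted p = 0.0108; adjusted p = 0.946 with an estimated correlation) ended without control replicate 3 (0.0816) or OE replicate 2 (0.327), and that of the matrix list without the same libraries (0.101 and 0.0908). Without the 4 libraries that stood apart 5728 genes passed, voom with quality weights gave 5833, and camera called 8 to 21 lists in the other splits of these libraries, against 12 of 35 in the real one.

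At day 4, mitosis and matrix genes had risen by several-fold in OE and fatty acid oxidation genes had fallen (n = 3 OE and 2 control libraries). The spindle gene Tpx2 rose from 1.54 ± 0.438 to 27.9 ± 6.87 CPM, a log2 fold change of 4.18 ± 0.44 (SE; edgeR adjusted p = 1.17e-05). Lox rose from 11.6 ± 0.864 to 376 ± 148 CPM (5.02 ± 0.46, edgeR adjusted p = 4.65e-06). Kcnip2, the subunit that shapes the transient outward potassium current, fell from 314 ± 5.81 to 3.44 ± 1.66 CPM (-6.49 ± 0.38, edgeR adjusted p = 1.83e-07). By edgeR 5256 genes changed (36.0%), 2624 higher and 2632 lower, 1428 and 1582 of them by at least 2-fold. The libraries of both groups did not overlap for 10669 genes (73.1%), where chance gives 20%.

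Most genes of the G2/M and G1/S lists rose at day 4. Of 28 G2/M and mitosis genes 26 rose and 1 fell (median 3.71), among them Tpx2, Anln (4.18 ± 0.45) and Prc1 (3.76 ± 0.42), which act in cytokinesis, and the survivin gene Birc5 (3.88 ± 0.50); adjusted over the list alone the counts were 26 and 1. Of 28 G1/S and DNA replication genes 22 rose and 6 did not pass (23 rose adjusted over the list alone; median 1.39), such as Gins2 (3.23 ± 0.43) and the ribonucleotide reductase genes Rrm2 (2.19 ± 0.34) and Rrm1 (1.46 ± 0.23). Of 26 p53 targets 13 rose, Zmat3 (1.70 ± 0.17) first, and 4 fell, Sesn1 (-2.69 ± 0.37) first (13 and 5 adjusted over the list alone; median 0.81). Camera called the 3 lists (adjusted p = 3.26e-15, 1.42e-08 and 0.0287), with adjusted p = 0.352, 0.39 and 0.352 with an estimated correlation; that of the p53 list ended without the 4 libraries that stood apart (0.0578). In the same OE libraries 4 of 17 macrophage markers were higher and 13 did not pass (camera adjusted p = 0.677 with an estimated correlation).

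Part of the matrix and signalling lists rose beside them. Of 35 matrix genes 26 rose and 9 did not pass (27 rose adjusted over the list alone; median 2.18), with Col12a1 (4.82 ± 0.41), Tgfb2 (3.50 ± 0.31), Lox and Cthrc1 (5.99 ± 0.57) first. Of 25 fetal and stress-response genes 17 rose, 1 fell and 7 did not pass (19 and 1 adjusted over the list alone; median 2.58); Myh7b fell by 4.31 on the log2 scale, while Gdf15 (4.17 ± 0.43), Ctgf (3.36 ± 0.40) and the protease inhibitor Timp1 (5.91 ± 0.75) rose. Of 28 inflammatory and NF-kB genes 13 rose (13 adjusted over the list alone; median 1.35), such as the cytokine Lif (3.53 ± 0.60), the chemokine Ccl7 (3.50 ± 0.71) and the prostaglandin synthase Ptgs2 (2.67 ± 0.58). Of 27 integrated stress response genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.98), led by Slc7a5 (2.61 ± 0.24). Camera's adjusted p for these 4 lists were 2.16e-13, 1.15e-07, 0.000783 and 0.00108, with adjusted p = 0.352, 0.352, 0.677 and 0.39 with an estimated correlation. The macrophage list, which shares no gene with the others, had a median of 1.24 with 4 of 17 markers higher (the same count adjusted over the list alone), Ccr2 (3.20 ± 0.47) and Lgals3 (3.51 ± 0.57) first (camera adjusted p = 0.00114; adjusted p = 0.677 with an estimated correlation). Endothelial markers went the other way: 11 of 17 fell, here and adjusted over the list alone (median -0.92), Aqp1 (-1.66 ± 0.33) and Kdr (-1.47 ± 0.32) first (camera adjusted p = 0.000722; adjusted p = 0.677 with an estimated correlation).

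Most mitochondrial metabolism genes and part of the excitation lists were lower at day 4. Of 51 oxidative phosphorylation genes 49 fell (median -0.98), Ndufs7 (-1.43 ± 0.21) and Cox7a1 (-1.64 ± 0.28) first; of 32 fatty acid oxidation genes 30 fell (median -1.62), with Echs1 (-2.02 ± 0.19), Slc27a1 (-2.94 ± 0.28) and Ucp3 (-4.34 ± 0.52) first; and of 23 tricarboxylic acid cycle genes 22 fell (median -1.09), Mdh1 (-1.86 ± 0.26) and Idh2 (-1.73 ± 0.28) first. Adjusted over the list alone 49, 31 and 23 fell. Of 27 ion channel genes 16 fell and 1 rose, the same counts as adjusted over the list alone (median -1.38), Kcnip2, the pacemaker channel gene Hcn2 (-2.42 ± 0.29) and Kcnd2 (-3.90 ± 0.50) first. Of 26 calcium handling genes 11 fell and 2 rose (median -0.59), Hrc (-3.26 ± 0.32), Trdn (-1.71 ± 0.21) and Pln (-2.92 ± 0.40) first; adjusted over the list alone the counts were 11 and 2. Camera called these 5 lists (adjusted p = 3.26e-15, 1.19e-15, 4.53e-09, 7.44e-06 and 0.00427), with adjusted p = 0.524, 0.352, 0.524, 0.39 and 0.352 with an estimated correlation. Of 26 sarcomere genes 8 fell, troponin Tnni3 (-1.76 ± 0.27) first, and 1, desmin (Des, 1.95 ± 0.41), rose, in both adjustments. Camera did not call that list (median -0.50, adjusted p = 0.211). Part of the interferon response list was lower as well (11 of 29 fell and 1 rose, in both adjustments; median -0.98; camera adjusted p = 0.00114, and adjusted p = 0.686 with an estimated correlation), with Gbp3 (-2.15 ± 0.57) and Ifit2 (-1.44 ± 0.40) first, whose calls ended without control replicate 1 (edgeR adjusted p = 0.0741 and 0.0835).

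Under the naming rule, the largest rises at day 4 were the chemokine receptor gene Cxcr6 (8.55 ± 1.23), Esr1, Sprr1a (7.42 ± 1.42), Nrip3 (6.98 ± 0.80) and the matrix glycoprotein gene Tnc (6.94 ± 0.77), and the largest falls Asb14 (-6.50 ± 0.39), Kcnip2, Cngb3 (-6.46 ± 0.62) and Kcnv2 (-6.29 ± 0.52). Without control replicate 1 the number of changed genes was 2757 and without replicate 2 it was 2740, each leaving 1 control library that is assumed to vary like the others; voom with quality weights gave 8997.

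At day 6, collagen and macrophage genes were higher in OE by many-fold and the calcium pump gene was lower (n = 3 and 3). Periostin (Postn), a matrix protein of activated fibroblasts, rose from 139 ± 13.4 to 5456 ± 1904 CPM, a log2 fold change of 5.29 ± 0.35 (SE; edgeR adjusted p = 2.04e-07). Atp2a2, which encodes the sarcoplasmic reticulum calcium pump, fell from 26357 ± 1196 to 3892 ± 1676 CPM (-2.76 ± 0.39, edgeR adjusted p = 6.37e-05). Cox7a1, the heart and muscle subunit of cytochrome oxidase, fell from 450.2 ± 19.5 to 75.2 ± 23.1 CPM (-2.58 ± 0.27, edgeR adjusted p = 5.90e-06). By edgeR 6494 genes changed (44.5%), 3409 higher and 3085 lower, 2234 and 1681 of them by at least 2-fold. The libraries of both groups did not overlap for 8912 genes (61.0%), where chance gives 10%.

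Most matrix, macrophage and inflammatory genes rose at day 6. Of 35 matrix genes 34 rose, in both adjustments (median 3.33), with Lox (6.52 ± 0.42), Postn, Cthrc1 (8.38 ± 0.57) and Col12a1 (4.93 ± 0.35) first. Of 17 macrophage and monocyte markers 16 rose (17 adjusted over the list alone; median 2.84), the monocyte chemokine receptor Ccr2 (4.85 ± 0.46), galectin Lgals3 (4.92 ± 0.54), Cd68 (3.37 ± 0.50) and Emr1 (2.87 ± 0.48) first. The mean log2 CPM of the macrophage markers was 7.22 in OE replicate 1 against 5.51 and 6.30 in the other OE libraries. Of 16 fibroblast markers 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.20), Col1a2 (3.93 ± 0.44), Col1a1 (4.23 ± 0.48), Mfap5 (4.01 ± 0.46) and Col3a1 (3.77 ± 0.52) first; the 11 markers outside the matrix list had a median of 0.77. Of 28 inflammatory and NF-kB genes 20 rose, in both adjustments (median 1.72), Nfkb2 (0.77 ± 0.12), the adhesion molecule Vcam1 (1.72 ± 0.29) and Lif (2.98 ± 0.58) first. Camera called the 4 lists (adjusted p = 9.33e-19, 2.06e-07, 0.00272 and 5.86e-06), with adjusted p = 0.421, 0.495, 0.772 and 0.606 with an estimated correlation. Part of the endothelial list was lower beside these: 7 of 17 fell, in both adjustments (median -0.61), Kdr (-1.66 ± 0.30) and Aqp1 (-1.33 ± 0.31) first (camera adjusted p = 0.0138; adjusted p = 0.772 with an estimated correlation).

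Most cell cycle genes and part of the stress lists were higher at day 6 as well. Of 28 G2/M genes 26 rose, in both adjustments (median 3.32), Anln (3.72 ± 0.37), Prc1 (3.41 ± 0.35) and Tpx2 (3.41 ± 0.36) first, and of 28 G1/S genes 24 rose (median 1.67), Rrm2 (2.54 ± 0.31) and Rrm1 (1.63 ± 0.20) first; for the G1/S list 24 rose and 1 fell adjusted over the list alone. Of 25 fetal and stress-response genes 15 rose and 1, Myh7b (-3.78 ± 0.35), fell (16 and 1 adjusted over the list alone; median 1.62), with osteopontin (Spp1, 8.35 ± 0.79) and Ctgf (3.51 ± 0.34) the first to rise. Of 27 integrated stress response genes 11 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.72), Slc7a5 (1.98 ± 0.21), Gdf15 (3.60 ± 0.41) and the proline synthesis gene Pycr1 (3.40 ± 0.42) first. Camera called these 4 lists (adjusted p = 1.03e-12, 1.18e-07, 4.10e-05 and 0.0129), with adjusted p = 0.421, 0.465, 0.421 and 0.591 with an estimated correlation. The atrial peptide gene Nppa, first in the atrial and conduction list, rose from 413 ± 357 to 8151 ± 3540.1 CPM (4.30 ± 0.72, edgeR adjusted p = 0.000235). The macrophage markers above were higher in the same OE libraries as the cell cycle genes.

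The 3 mitochondrial metabolism lists fell nearly whole at day 6, when the macrophage markers were highest. All 51 oxidative phosphorylation genes tested fell (median -1.56), Cox7a1, Ndufs7 (-1.77 ± 0.19) and Ndufb10 (-1.80 ± 0.21) first. Of 32 fatty acid oxidation genes 30 fell (31 adjusted over the list alone; median -2.19), Eci1 (-2.86 ± 0.22), Acaa2 (-2.79 ± 0.22) and Echs1 (-2.32 ± 0.18) first, and all 23 tricarboxylic acid cycle genes tested fell (median -1.73), Idh2 (-2.56 ± 0.27) and Suclg1 (-1.86 ± 0.21) first. For the respiratory and cycle lists the counts adjusted over the list alone were the same. Of 27 ion channel genes 18 fell and 1 rose (median -1.54), Kcnip2 (-5.92 ± 0.37), Kcnj11 (-2.73 ± 0.29) and Scn4b (-4.76 ± 0.57) first, and of 26 calcium handling genes 12 fell and 1 rose (median -0.73), the calcium store protein Hrc (-3.88 ± 0.32) and the kinase Camk2b (-1.67 ± 0.20) first. Of 23 cardiac transcription factors 11 fell and 1 rose (median -0.70), Rxra (-0.94 ± 0.12), Klf15 (-2.04 ± 0.27) and Ppara (-2.81 ± 0.38) first. Adjusted over the list alone 18, 12 and 11 genes of these 3 lists fell. Camera called the 6 lists (adjusted p = 1.15e-22, 1.66e-18, 3.97e-13, 1.07e-06, 0.007 and 0.000988), with adjusted p = 0.421, 0.421, 0.421, 0.421, 0.421 and 0.701 with an estimated correlation. Of 26 sarcomere genes 9 fell and 1 rose (the same counts adjusted over the list alone), Tnni3 (-2.12 ± 0.25), Myl3 (-1.90 ± 0.29) and Cmya5 (-2.46 ± 0.43) first; the call of that list (median -0.56, camera adjusted p = 0.0112; adjusted p = 0.772 with an estimated correlation) ended without OE replicate 1 (0.187) and without the 4 libraries that stood apart (0.176).

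The largest rises at day 6 under that rule were Sprr1a (9.44 ± 1.33), Cthrc1, Spp1 and Esr1, followed by P4ha3, a collagen prolyl hydroxylase subunit whose 3 control counts gave a ratio of 286 (95% counting interval 97.5 to 1387). Among the largest falls, Lrrc52 had 1 count over the OE libraries and was 119-fold lower (20.8 to 4774), followed by Acsm5 (-5.94 ± 0.66) and Kcnip2. Camera called 9 to 23 lists in the other splits of the day 6 libraries, against 17 of 35 in the real one. The gene counts within each list do not rest on camera, but the genes of a list are correlated and are not independent evidence.

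**Figure D3:**
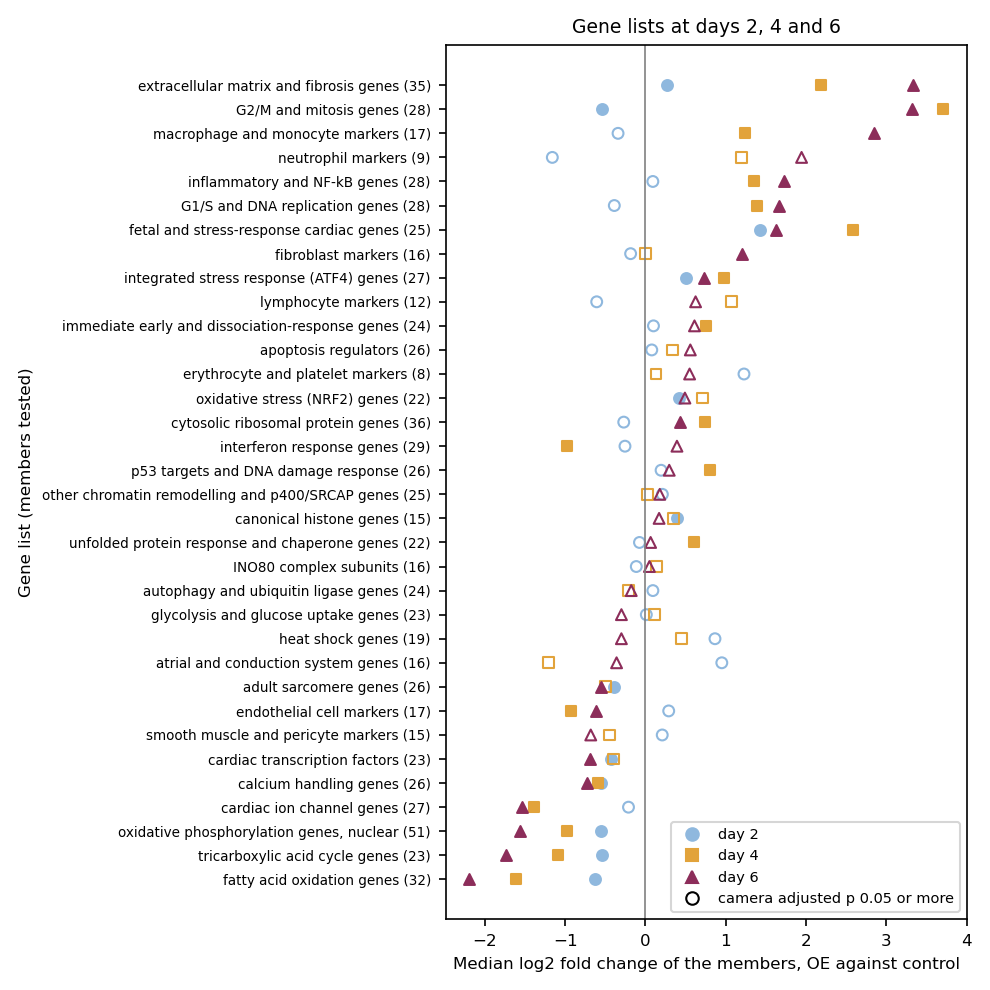
Median log2 fold change, OE against control, of 34 gene lists at days 2, 4 and 6; filled points have a camera adjusted p under 0.05 with the preset correlation of 0.01. G2/M genes go from -0.55 at day 2 to 3.71 and 3.32 at days 4 and 6, and fatty acid oxidation genes from -0.62 to -1.62 and -2.19.

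**Figure D4:**
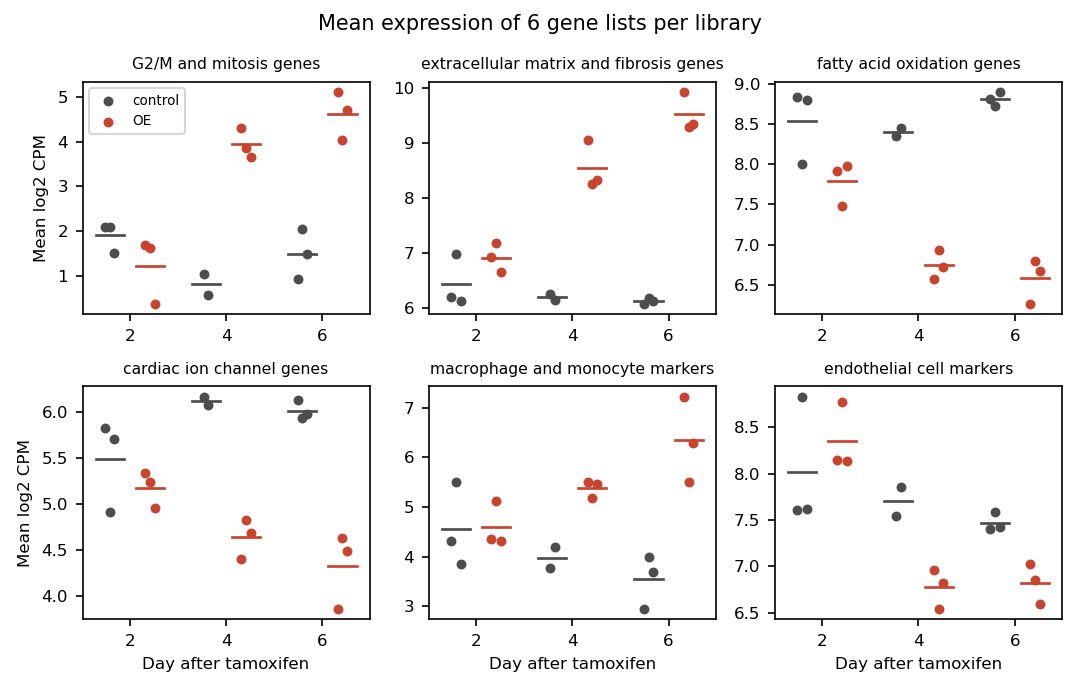
Mean log2 CPM per library of chosen gene lists, by day and group, each point 1 library and bars the group means. The macrophage list reaches 7.22 in day 6 OE replicate 1, against 5.51 and 6.30 in the other OE libraries of that day.

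The interaction contrasts asked which OE effects differed between days. Among the lists, mitosis genes moved most: the OE effect on the G2/M list was higher at day 4 than at day 2 by a median log2 difference of 4.30, with 26 of 28 genes past edgeR's test, Tpx2 (5.01 ± 0.56, adjusted p = 0.000221) among them. From day 2 to day 6 the effect on the matrix list rose by 2.91, with 27 of 35 genes past the test, Postn (5.04 ± 0.44, edgeR adjusted p = 2.25e-05) among them, and that on macrophage markers by 3.16 (15 of 17). The effects on fatty acid oxidation genes fell by 1.61 over the same span, with 23 of 32 genes past the test downward and 1 upward. Camera's adjusted p for these 4 differences were 9.35e-23, 6.90e-19, 3.59e-08 and 4.74e-13, with adjusted p = 0.577, 0.537, 0.615 and 0.537 with an estimated correlation. In all, the effects of 2120 genes differed between days 2 and 4 (1073 higher at day 4, 1047 lower) and those of 3355 between days 2 and 6 (1827 higher at day 6, 1528 lower). The 4 genes that shared the lowest adjusted p in the first contrast included Selenbp1 (-2.54 ± 0.23, edgeR adjusted p = 0.000103) and the general transcription factor gene Taf7 (-3.01 ± 0.28, 0.000103). Between days 4 and 6 edgeR called 2 genes, Klhdc8a (-2.12 ± 0.30) and Leo1 (-1.87 ± 0.28; adjusted p = 0.0469 for each), both lower, against 2755 at an unadjusted p under 0.05, 594 by DESeq2 and 3145 by voom. The count for days 2 and 4 was 835 without day 4 control replicate 1, 900 without control replicate 2 and 1373 without OE replicate 1. For days 4 and 6 it was 261 without day 2 OE replicate 3, 117 without day 2 control replicate 2, 8 without day 6 OE replicate 2 and 2 without day 2 control replicate 1. Leaving out any 1 other library ended both calls (adjusted p = 0.0515 to 0.378), with 1 other gene called by edgeR without day 4 control replicate 2 and 0 in the remaining cases.

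Days shared more changed genes than the product of their shares gives. Days 4 and 6 shared 3524 genes changed in the same direction (1169 expected) and 25 in opposite directions, with a Spearman correlation of log2 fold changes across genes of 0.73. Days 2 and 4 shared 1329 (500 expected; 122 opposite; 0.32), and days 2 and 6 shared 1435 (617 expected; 159 opposite; 0.31). At all 3 days 355 genes were higher and 687 lower, Ino80, Gdf15 and Slc7a5 among the former and Pln, Trdn, Ppara and Klf15 among the latter. Genes are not independent replicates, and each day had its own control libraries.

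Control libraries were compared between days to show what moved without Ino80 overexpression. At day 4 the immediate early gene Fos was lower than at day 2 (11.6 ± 0.959 against 249 ± 146 CPM; -4.43 ± 0.52, edgeR adjusted p = 0.00536; n = 2 and 3), as were the chemokines Cxcl2 (-6.09 ± 1.02) and Cxcl1 (-5.46 ± 0.86). These were among 19 genes, 3 higher and 16 lower. At day 4, 1409 passed at an unadjusted p under 0.05. At day 6 the chemokines Ccl4 (-4.82 ± 1.05), Cxcl2 (-3.66 ± 0.75) and Cxcl1 (-3.21 ± 0.64) were lower than at day 2, and Klhdc8a (1.85 ± 0.20) and Slc41a3 (1.83 ± 0.23) were higher, among 385 genes (92 higher, 293 lower; n = 3 and 3). In a fit to the control libraries of all days alone edgeR called 0 genes at day 4 (adjusted p = 0.240 for those named) and 36 at day 6. With a replicate-number block shared across days added to that fit, it called 1 and 16. The labels state no such sharing. DESeq2 called 127 and 1299 and voom 690 and 2605. The calls of the 3 chemokines at day 6 ended in the control-only fit and with the block, and those of Klhdc8a and Slc41a3 with the block (edgeR adjusted p = 0.0551 to 0.0678). The day 6 count was 7, 11 and 5 without control replicates 1, 2 and 3 of day 6, and 119 without day 2 control replicate 2, each of which ended the 3 chemokine calls (adjusted p = 0.0653 to 0.148). It was 658 without day 2 control replicate 1, 237 without day 2 OE replicate 1, 692 without day 2 OE replicate 3, 200 to 225 without any 1 of the 5 day 4 libraries, 648 without day 6 OE replicate 1 and 248 without OE replicate 3. The day 4 count was 0 without day 4 control replicate 1, 1 without replicate 2, both of which ended the named calls (adjusted p = 0.0948 to 0.669), 70 without day 2 control replicate 1, 8 without control replicate 3, 38 without day 2 OE replicate 3, 8 to 11 without any 1 of the day 4 OE libraries, 8 to 12 without any 1 of the day 6 control libraries, and 9 and 10 without day 6 OE replicates 2 and 3. The day 4 calls of Cxcl2 and Cxcl1 also ended without day 2 control replicate 3 (edgeR adjusted p = 0.0545), and that of Cxcl2 without day 4 OE replicate 2 or 3, day 6 control replicate 2 or 3, or day 6 OE replicate 2 (0.0501 to 0.0609). Day and library batch cannot be told apart in these comparisons.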

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

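All tests of explanations in this part, the comparisons with other splits of the libraries included, were chosen after the results were seen.

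Several OE effects, meaning differences of OE from control libraries, differed between days by the interaction test. They may be confounded with effects of a driver carried by the OE line, as set out below. EdgeR found 2120 such genes between days 2 and 4, 3355 between days 2 and 6 and 2 between days 4 and 6. From day 2 to day 4 the genes with the lowest adjusted p had log2 differences of 5.52 (Adam12), 1.66 (Acp1), 5.01 (Tpx2) and 2.51 (Hn1l) upward and -2.54 (Selenbp1), -3.01 (Taf7), -3.29 (Csdc2) and -2.84 (Slc26a6) downward. From day 2 to day 6 they had 5.04 (Postn), 3.71 (Ddah1), 5.61 (Cdca3) and 4.84 (Loxl3) upward, and -4.12 (Taf7), -3.61 (Klhdc8a), -3.63 (Csdc2) and -2.39 (Selenbp1). From day 4 to day 6 the differences were -2.12 for Klhdc8a and -1.87 for Leo1. Klhdc8a rose in control libraries from day 2 to day 6 (log2 fold change 1.85), so its difference between those days rests in part on the controls. Lists with at least 10 members past the test from day 2 to day 4 had median log2 differences of 1.69 (G1/S), 4.30 (G2/M), -1.02 (ion channels), -0.88 (fatty acid oxidation), 1.77 (inflammatory) and 1.90 (matrix). From day 2 to day 6 they were 1.96 (G1/S), 3.90 (G2/M), -1.34 (ion channels), -0.98 (oxidative phosphorylation), -1.61 (fatty acid oxidation), -1.22 (tricarboxylic acid cycle), 1.90 (inflammatory), 2.91 (matrix) and 3.16 (macrophage markers). The inflammatory differences may rest in part on the controls. Its members Cxcl1 and Cxcl2 fell in control libraries from day 2 to day 4 (log2 fold changes -5.46 and -6.09) and to day 6 (-3.21 and -3.66). These were among the largest control falls, and the list as a whole was not tested between control days. From day 4 to day 6 the median differences with the lowest camera adjusted p were -0.54 for oxidative phosphorylation, 1.47 for interferon response, 1.12 for matrix and 1.44 for fibroblast markers, with adjusted p = 0.85 with an estimated correlation for each.

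Other splits of the libraries bear on these counts. For the difference between days 2 and 6, 3 of 100 splits drawn of 200 gave as many genes, the real one included (3355, highest other 4729), a share under 0.05 that rests on how the OE libraries are parted. The 9 splits that keep every OE library in its day gave 2300 to 4729 genes, 3 of them as many as the real one, and the other 91 gave 0 to 1. Since 3 OE libraries against 3 can be parted in 10 ways, this share carries no more weight than those that follow. For OE against control, 3 libraries against 3 also make 10 splits, too few for a share under 0.05. At day 2 the real count was 2781 genes and the highest other 1065, in the split that parts control replicates 1 and 3 and OE replicate 3 from the rest; at day 6 the counts were 6494 and 0, and for control at day 6 against day 2 they were 385 and 0 (1 of 10 splits as large in each). At day 2, where same-number libraries correlated, 1 of the 4 splits that part all 3 same-number pairs gave as many genes, with 0 in the others. Counts of called lists were 12 at day 2 with 21 the highest other (8 of 10 splits as large) and 17 at day 6 with 23 the highest other (6 of 10 splits). The counts of changed genes within a list do not use camera, but the members are correlated and are not independent evidence. At day 2 the estimated correlation was 0.844 for oxidative phosphorylation genes and 0.912 for tricarboxylic acid cycle genes.

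Counts assigned to Esr1, A1cf and Gt(ROSA)26Sor set the OE libraries apart. A difference in depth is argued against: unscaled Esr1 counts were at least 263-fold higher in OE as a ratio of means at each day, while mean totals differed by ratios of 1.11, 0.935 and 1.28. A library with the label of the other group is argued against by 0 of 17 libraries with an Ino80 level on the other group's side. All 9 OE libraries were above every control library for all 3 genes, which sequence of a tamoxifen-inducible Cre driver and of a Rosa26 cassette counted as these genes would also give. Gene counts hold no junction reads, so that this and higher expression of the endogenous genes cannot be told apart. An effect of such a driver under tamoxifen may be confounded with that of Ino80, since the controls hold these counts at lower levels (0 counts for A1cf).

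Matrix, fibroblast and macrophage lists had medians above 0 in OE against control at day 6. A lower share of cardiomyocytes that raises every other cell type alike is argued against by endothelial markers. Their median log2 fold change was -0.61, against 2.84 for macrophage markers. Over libraries, the differences in list median were -0.63 (95% interval -1.01 to -0.24) and 2.74 (1.11 to 4.37). More fibroblasts with their usual profile are argued against by the 11 fibroblast markers outside the matrix list. Their median minus that of the matrix list was -2.55, and -2.45 over libraries (-3.02 to -1.89). Macrophages in the preparations are a candidate source, in line with 16 of 17 markers past the gene test and with levels of 522, 262 and 219 CPM of Lyz2, Mrc1 and Csf1r in OE against 81.5, 55.0 and 53.4 CPM in control; the list shares no gene with the others, and the labels name no sort that would remove these cells. Activated fibroblasts or matrix genes expressed by cardiomyocytes stay open, as the counts carry no cell identity.

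Oxidative phosphorylation, fatty acid oxidation and tricarboxylic acid cycle lists had medians below 0 in OE against control at all 3 days. With a gene length trend removed at day 2, the oxidative phosphorylation median went from -0.56 to -0.28, and over libraries the difference in that median was then -0.34 (95% interval -1.02 to 0.34 unpaired, -0.55 to -0.13 paired by number, -0.36 to -0.21 for the median by resampling genes). For fatty acid oxidation and tricarboxylic acid cycle genes the medians went from -0.62 to -0.44 and from -0.54 to -0.45. With the trend removed, their intervals over libraries were -1.58 to 0.52 and -1.45 to 0.49 unpaired. Paired by number they were -1.02 to -0.05 and -0.93 to -0.03. Without that correction the unpaired intervals of the 3 lists also held 0 (-1.21 to 0.03, -1.50 to 0.29 and -1.33 to 0.30). Paired and unpaired forms disagree, and the labels state no pairing. The trend as the whole cause at day 2 and a fall beyond it therefore cannot be told apart. Dilution by other cells as the whole cause at day 6, lowering all cardiomyocyte RNA alike, is argued against by oxidative phosphorylation genes set against sarcomere genes. The median log2 fold change of the former minus that of the latter was -1.01, and -0.87 over libraries (-1.40 to -0.34). This takes sarcomere genes as unchanged within cardiomyocytes, which was not tested. Dilution beside a change of the sarcomere genes therefore stays open. Scaling is argued against by an oxidative phosphorylation median of -1.32 at day 6 under raw totals, the scaling that moved it most. That Ino80 overexpression lowers these genes may be held as a hypothesis, found and tested on the same data, with the driver, the cell mixture and, at day 2, gene length still open.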

How the results depend on the processing

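The alternatives without 4 libraries and with gene length removed were chosen after seeing the data; the others were fixed before the data were examined. Of 466 named-gene results (460 with the compared days alone and 465 without 4 libraries), the number that lost the call was 6 under DESeq2, 3 under voom, 11 with no filter, 74 with the compared days alone, 35 with the replicate block, 4 under RLE factors, 13 with a sex covariate, 84 without some 1 library and 12 without 4 libraries. Of 105 list results (35, those of day 2, with gene length removed, and 102 without 4 libraries) it was 47 with an estimated correlation, 14 under fry, 1 with gene length removed (the day 2 sarcomere list, at 0.134, which that form of test did not call before the correction either, at 0.0828; at day 6 the sarcomere and endothelial lists likewise went from 0.0505 to 0.0863 and from 0.0542 to 0.0673), 6 without some 1 library, 4 without 4 libraries and 0 in the other settings, with the compared days alone giving 101 results. Where a result moved, the cause was not tested, apart from fewer libraries in those that leave some out. The sex covariate marks day 4 OE replicate 1 alone, the only library with a female pattern. It therefore works much like leaving that library out and is no separate check of sex.

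Genes changed at day 2 (2781) numbered 5833 under voom, 423 with day 2 alone, 5728 without 4 libraries and 1858 to 3726 as each library was left out. At day 4 (5256) the counts were 8997 under voom and 2740 to 6291, and at day 6 (6494) 5338 to 7422. Differences between days 2 and 4 (2120) came to 6086 (voom), 1345 (compared days), 1378 (sex), 5101 (without 4) and 835 to 2966, and those between days 2 and 6 (3355) to 5410 (voom) and 2445 to 3648. Between days 4 and 6 (2; 2755 unadjusted) there were 594 by DESeq2, 3145 by voom, 1097 with the compared days, 1783 without 4, 0 under RLE factors, the block or the sex covariate, and 0 to 261. Control at day 4 against day 2 (19; 1409 unadjusted) gave 127 (DESeq2), 690 (voom), 0 (control alone), 1 (control alone with a block), 10 (sex), 94 (without 4) and 0 to 70. Control at day 6 against day 2 (385) gave 1299 (DESeq2), 2605 (voom), 36 (control alone), 16 (control alone with a block), 196 (sex), 1274 (without 4) and 5 to 692. With an estimated correlation camera called 0 lists at days 2, 4 and 6 against 12, 18 and 17, with 2, 3 and 3 at an unadjusted p under 0.05; fry called 8, 17 and 19, and leaving out each library gave 12 to 17, 18 to 21 and 16 to 21. At a threshold of 0.01 days 2 and 4 shared 559 genes, days 4 and 6 2056 and days 2 and 6 698. Same-number libraries correlated at day 2 (0.276, 0.337 and 0.271) and not at days 4 and 6. The labels state no pairing, and at day 6 libraries of unlike number reached 0.269 and 0.247. With the block 2428, 4509 and 6403 genes changed at days 2, 4 and 6.

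Direction reversed for Fabp4 at day 2 (0.64 without 4 libraries, -0.52 to 0.56 as each library was left out), for Csf3r (1.11 under voom, 1.36 without 4, and -0.95 to 1.39 as each library was left out, the highest without day 2 control replicate 2) and S100a9 (1.56, 2.13, and -2.48 to 2.22), all 3 not past the test as reported, and for Xist at day 4 (-0.12 under voom, -2.17 with a sex covariate, against 6.44), which rests on 1 library. Scaling by raw totals moved the median of all genes to 0.11, 0.14 and 0.31 at days 2, 4 and 6, from 0.00, 0.02 and 0.05 with TMM, and turned that of the unfolded protein response list at day 2 from -0.07 to 0.04. On simulated counts edgeR recovered 16, 50 and 88% of genes changed 1.5, 2 and 4-fold at day 2, and 4, 54 and 86% at day 6. Each of these simulations changed 200 genes, far fewer than the 2781 and 6494 called at days 2 and 6. The shares recovered therefore need not hold for the real libraries. All 3 list tests found a fatty acid oxidation list lowered 1.5-fold. The simulated genes varied independently, whereas the real list had an estimated correlation of 0.593 at day 2. The simulation therefore does not show the power of the list tests on the real libraries. DESeq2 recovered 70 and 72% of genes changed 2-fold at days 2 and 6. It also called 25 and 33 of the 14143 and 14128 unchanged genes, against 5 and 3 by edgeR.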

Other observations

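The gene and list tests in this part were fixed before the data were examined; leaving out the 4 libraries together was chosen after the results were seen.

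Part of the protein synthesis and folding lists rose at day 4. Of 36 cytosolic ribosomal protein genes 15 rose (31 adjusted over the list alone; median 0.74), Rpl3 (1.54 ± 0.36) first, and of 22 unfolded protein response genes 12 rose and 1 fell, in both adjustments (median 0.60). Herpud1, an endoplasmic reticulum degradation gene, fell (-2.33 ± 0.27), while Manf (1.17 ± 0.24) and Sdf2l1 (1.91 ± 0.42) rose. Of 24 immediate early and dissociation-response genes 10 rose and 1 fell (median 0.75), and 10 and 2 adjusted over the list alone. Egr2 (16.5 ± 5.03 CPM in OE against 0.491 ± 0.281 in control), Egr3 (log2 2.84 ± 0.51) and Myc (2.56 ± 0.49) came first. Camera's adjusted p for the 3 lists were 5.79e-07, 0.00447 and 0.00524, with adjusted p = 0.677, 0.637 and 0.677 with an estimated correlation. At day 6 4 ribosomal protein genes rose (1 adjusted over the list alone; median 0.44; camera adjusted p = 0.00492, and adjusted p = 0.772 with an estimated correlation). These 4 of 36 are a smaller share than over all genes tested at that day, where 3409 of 14604 rose. Glycolysis genes split: at day 4 4 of 23 rose and 5 fell, in both adjustments, with the lactate transporter Slc16a3 (4.55 ± 0.41) and Pgam1 (1.64 ± 0.19) higher and the insulin-responsive glucose transporter Slc2a4 (-2.83 ± 0.33) and muscle phosphofructokinase Pfkm (-2.50 ± 0.33) lower; camera did not call the list (adjusted p = 0.831). Slc16a3 (3.88 ± 0.35), Slc2a4 (-2.84 ± 0.32) and Pfkm (-2.68 ± 0.31) kept their directions at day 6. At day 2 the median of that list was 0.01 while camera's direction was down.

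At day 2 the NRF2 list held 7 rises and 2 falls among 22 genes (8 and 3 adjusted over the list alone; median 0.42), Srxn1 (4.26 ± 0.67) and Gclc (1.85 ± 0.33) first, with CPM of 619 ± 693 and 101 ± 70.7 in OE (mean ± SD). Camera's call (adjusted p = 0.0108; adjusted p = 0.919 with an estimated correlation) ended without OE replicate 3 (0.189) and without the 4 libraries that stood apart (0.0839), and both genes' calls ended in a fit to day 2 alone (edgeR adjusted p = 0.0538 and 0.085). Of 15 histone genes 4 rose, in both adjustments (median 0.40), a call (camera adjusted p = 0.0171; adjusted p = 0.746 with an estimated correlation) that ended without OE replicate 1 (0.0597). Among lists that camera called at no day, the heat shock list had medians of 0.87, 0.45 and -0.30 at days 2, 4 and 6. At day 6 autophagy genes had 9 falls and 3 rises of 24, in both adjustments (median -0.18), Map1lc3b (-0.85 ± 0.12) first. Smooth muscle and pericyte markers had 7 falls and 4 rises of 15, in both adjustments (median -0.68), Abcc9 (-2.85 ± 0.36) and Kcnj8 (-1.54 ± 0.22) first. The chromatin remodeller gene Hells rose at days 4 and 6 (2.55 ± 0.32 and 2.79 ± 0.30), within a chromatin list of 25 genes with 4 rises at day 6 (3 adjusted over the list alone). The interferon list, part of which was lower at day 4, had 4 rises of 29 at day 6 (3 adjusted over the list alone), Mx1 (2.80 ± 0.67) and Cxcl10 (2.85 ± 0.76) first. For the chromatin and interferon lists these are smaller shares than over all genes tested at day 6, where 3409 of 14604 rose.

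At day 6 the neutrophil markers had a median of 1.94 with 3 of 9 higher (1 adjusted over the list alone), Csf3r (3.26 ± 0.77) first, and 1 of 12 lymphocyte markers, Il7r (3.20 ± 0.90), was higher in both adjustments, a call that ended without OE replicate 1 (edgeR adjusted p = 0.0665). Il1r2, with 3 control counts, had a ratio of 13.1 (95% counting interval 4.26 to 65.2), and Dio3, with 1 control count, one of 258 (46.1 to 10221). The median, mean and camera direction of a list differed in sign for INO80 subunits, glycolysis, immediate early, inflammatory, macrophage, neutrophil and sex-linked genes at day 2, for sex-linked genes at day 4 and for heat shock genes at day 6. None of these lists was called on that day.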
